A study of Homo sapiens with 6 samples.

How the data were processed

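The data were RNA sequencing libraries of HK-2 cells, 3 per group and 6 in all, each from cells deficient in DDX18 that had gone through hypoxia and reoxygenation and had received the WT or the K116R form. Per the labels, RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina. Whether the RNA was selected for polyA tails is not given in the sources used here. Groups and replicate numbers were taken from the labels.

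Per the submitters' processing notes, CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used with the human genome build GRCh38 (hg38). The gene counts are whole numbers as deposited by the authors, not normalized. The authors also deposited FPKM values for the same genes and samples, and the way these were computed, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Division of counts by FPKM and gene length gave, for each library, a denominator of 0.971 to 1.01 times its total count, so FPKM values had been scaled to a quantity near, but not equal to, the total. All 58735 genes of the table matched GENCODE release 29 (Ensembl 94) in position, strand and name, and 25069 of them had no count. Reads of genes that overlap on either strand, and of genes with pseudogenes or near-copies, could be assigned differently under other counting rules. The shares of exon bases given in the text come from that annotation.

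Total counts per library were between 13664277 and 14618362, and the 10 most abundant genes took between 17.9% and 21.0% of them. Pairs of replicates were compared by a chi-square test over genes with at least 20 counts. The chi-square per degree of freedom was 2.29 to 3.71 in WT, 2.40 for K116R replicates 2 and 3, and 8.93 and 10.5 for the pairs with K116R replicate 1, so no pair differed by sampling noise alone and each library was counted as 1 sample. Because the labels do not tie replicates to separate cultures, n counts libraries. Simulated counts for 16958 genes with the means and library sizes of the real samples were used to test the procedure. The 200 changed genes were drawn from those with an expected count above 50, so recovery was not tested for genes with fewer counts. At folds of 1.25, 1.5, 2 and 3, 38%, 78%, 100% and 98% of 50 genes each were recovered, with 12 false calls (7.1% of calls). With no gene changed there was 1 call. With a GC slope added to K116R replicate 1, 14%, 74%, 96% and 100% were recovered at these folds, with 6 false calls (4.1% of calls). With the GC correction 30%, 86%, 96% and 100% were recovered, with 8 false calls (4.9% of calls). No slope was added to the other libraries, so false calls under a GC trend that follows the groups were not tested. In a simulation with a shifted gene list, camera recovered it with the preset and with the estimated correlation (adjusted p = 0.018), and no other list was called. Genes were drawn independently in all of these simulations, so they do not test false calls among genes, or lists of genes, that vary together.

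Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), TMM factors were applied, and K116R was compared with WT by the quasi-likelihood F test with robust dispersion, group being the only term. P-values were adjusted by Benjamini and Hochberg over the 16958 genes tested, with a threshold of 0.05. The biological coefficient of variation was 7.14%. CPM values are counts scaled by TMM-adjusted library size, given as mean ± SD over the 3 libraries. Values of DDX18 and CD44 were also compared by an exact two-sided permutation test over the 10 splits. Overlaps and summaries were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots with matplotlib 3.10.9.

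Of 34 gene lists, 31 had at least 5 genes tested and were compared with all other genes by camera from limma with a preset correlation of 0.01, two-sided and adjusted over the 31 lists. Of these, 10 passed, 2 higher and 8 lower. With a correlation estimated for each list none passed after adjustment and 5 passed at an unadjusted p under 0.05, and by fry, which asks whether a list's genes move one way on balance, 13 passed. Some lists share members.

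The comparison, the test, the gene lists, the rule for the genes named and the other choices of processing, except the GC corrections, were chosen before the data were examined. The rule took DDX18 and CD44, the 10 largest rises and 10 largest falls among protein-coding genes that passed, had a mean of at least 2 CPM and did not overlap between groups, up to 4 members with the smallest p of each list discussed, and the 5 genes of highest mean CPM that passed. A gene that this rule takes is not reported here. EGFL7 and the noncoding genes MALAT1, NEAT1 and the mitochondrial tRNA genes named were chosen after their values were seen.

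Other choices tried were DESeq2 1.42.0, limma-voom, other scalings (DESeq2 size factors, upper quartile, library size only), other filters (none, or 1 CPM in 3 samples), protein-coding genes only, a gene-length correction, the replicate number as a block with and without that correction, limma on log2(FPKM + 1) with a mean FPKM of at least 0.5, the same with a pseudocount of 0.1 or without a filter, and leaving out each library in turn. Corrections for GC content, for GC content with gene length, the block with the GC correction, and the GC correction without K116R replicate 1 were chosen after seeing the data. Each correction was a per-library offset, a smooth (span 0.5) of each gene's log count deviation on the GC content of its longest transcript or on log gene length. A fold change on the log2(FPKM + pseudocount) scale understates the change of low genes.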

Results

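RNA sequencing was carried out on HK-2 cells, an established line of human renal proximal tubule epithelium, after hypoxia followed by reoxygenation. The cells were deficient in DDX18, a DEAD-box RNA helicase of the nucleolus, and had been given back either wild-type DDX18 (WT, n = 3) or a form with lysine 116 replaced by arginine (K116R, n = 3). Arginine keeps the positive charge of lysine and cannot take the acyl marks, lactylation among them, that lysine side chains carry. The single comparison, K116R against WT, asks which transcripts differ between cells with the 2 forms. Each library held between 13664277 and 14618362 counts, and between 26219 and 26989 genes had at least 1 count. Transcripts of the mitochondrial genome and its RNA genes took 17.2%, 18.7% and 17.6% of the counts in WT replicates 1 to 3 and 17.9%, 20.7% and 21.1% in K116R replicates 1 to 3. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. All samples were exposed to hypoxia and reoxygenation and received DDX18, and cells without either were not analysed here.

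DDX18 RNA itself was lower with K116R. DDX18 (ENSG00000088205, chromosome 2, 117814650 to 117832379, plus strand, GRCh38) stood at 152 ± 5.75 CPM (counts scaled to library size, SD, n = 3) with WT and at 80.3 ± 5.37 CPM (SD, n = 3) with K116R, which is 47.2% lower. Its log2 fold change was -0.92 (SE 0.066, edgeR adjusted p = 1.2e-08), and -1.01 with a correction for GC content. The counts do not separate RNA of the construct from RNA of the cells' own gene, nor the mutated codon from the normal one, and 5 annotated pseudogenes carry the gene's name. CD44, the hyaluronan receptor named in the series title, was also lower. CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402, plus strand) stood at 260 ± 13.0 CPM (SD, n = 3) with WT and 211 ± 3.78 CPM (SD, n = 3) with K116R, 18.9% lower, with a log2 fold change of -0.30 (SE 0.057, edgeR adjusted p = 0.0018) and of -0.32 with the GC correction. On the deposited FPKM values, CD44 had a log2 fold change of -0.30 and missed the threshold (limma adjusted p = 0.069). CTGF (also called CCN2), a secreted matricellular protein of fibrotic tissue, went the other way, from 130 ± 2.21 CPM (SD, n = 3) to 236 ± 15.5 CPM (SD, n = 3), a log2 fold change of 0.86 (SE 0.061, edgeR adjusted p = 1.2e-08). For DDX18 and for CD44 every K116R library lay below every WT library, and an exact two-sided permutation test gave p = 0.1 for each, the smallest that 3 against 3 samples can reach. Because DDX18 RNA differed between the groups, the form and the amount of DDX18 changed together in this comparison.

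**Figure D1:**
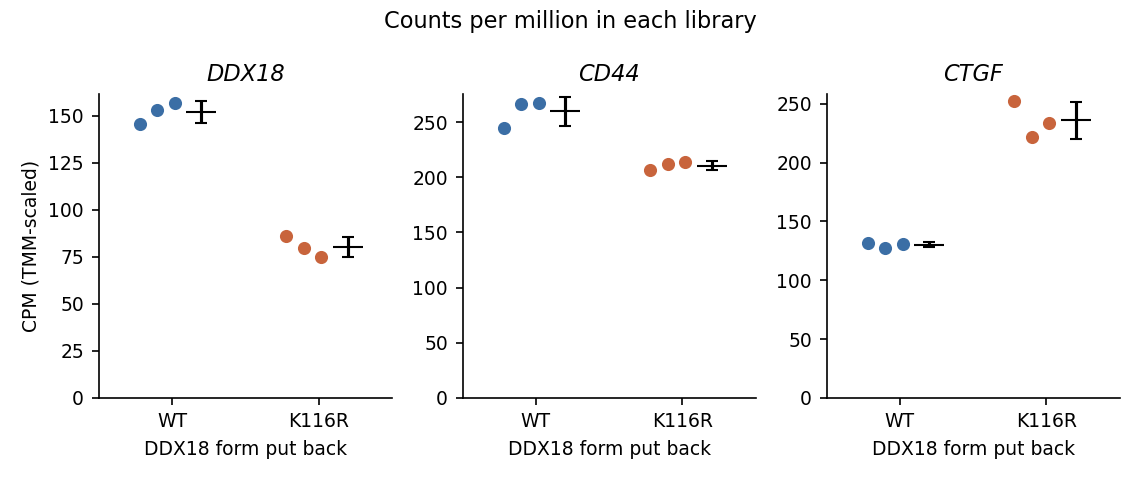
CPM (vertical axis, scaled with TMM factors) of DDX18, CD44 and CTGF in each of the 6 libraries, with the group mean and SD (n = 3) as the black mark and bar beside the points. DDX18 fell from a mean of 152 to 80.3 CPM and CD44 from 260 to 211 CPM, and CTGF rose from 130 to 236 CPM.

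Across the transcriptome, most differences were small. Of 16958 genes tested, 1524 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 702 higher and 822 lower with K116R, and 1369 of them were protein-coding. The median size of these changes was 1.27-fold, and 62 genes changed at least 2-fold, 29 upwards and 33 downwards. For 28.5% of all genes tested the 3 values of one group all lay above those of the other. Chance gives 10% for each single gene. Genes of the same libraries vary together, so a trend across whole libraries could also raise this share, and it is not a test. Leaving out WT replicate 1 or WT replicate 3 lowered the count of changed genes to 408 and 428, and the 2-fold counts without them were 24 and 36. Without WT replicate 2 the higher genes numbered 442, and without WT replicates 1 and 3 there were 172 and 161 higher and 236 and 267 lower genes. With limma on the deposited FPKM values 86 genes passed, and 3530 at an unadjusted p under 0.05. With library size in place of TMM scaling, 463 genes were higher and 1101 lower, so the share of higher genes among the changed ones was 29.6% in place of 46.1%. Libraries also differed by GC content. Across 11156 expressed protein-coding genes, which are not independent replicates, the deviation of a library from the mean of the 6 correlated with GC content at a Spearman rho of 0.61, 0.096 and 0.40 in WT replicates 1 to 3 and of -0.72, -0.11 and 0.083 in K116R replicates 1 to 3. The log2 fold change correlated with GC content at a rho of -0.53, and at -0.31 without K116R replicate 1. With gene length the deviations correlated at a rho of -0.26, -0.11 and -0.21 in WT replicates 1 to 3. In K116R replicates 1 to 3 these values were 0.26, 0.076 and 0.11, so the groups separated by gene length too. The log2 fold change correlated with gene length at a rho of 0.26, shorter genes tending to be lower with K116R. With a GC correction, added after seeing the data, 2146 genes changed, 1122 higher and 1024 lower, and 1153 of the 1524 (75.7%) kept call and direction. Without K116R replicate 1, 1676 genes changed, and with the GC correction as well 1905. None of the changed genes changed direction with that correction.

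**Figure D2:**
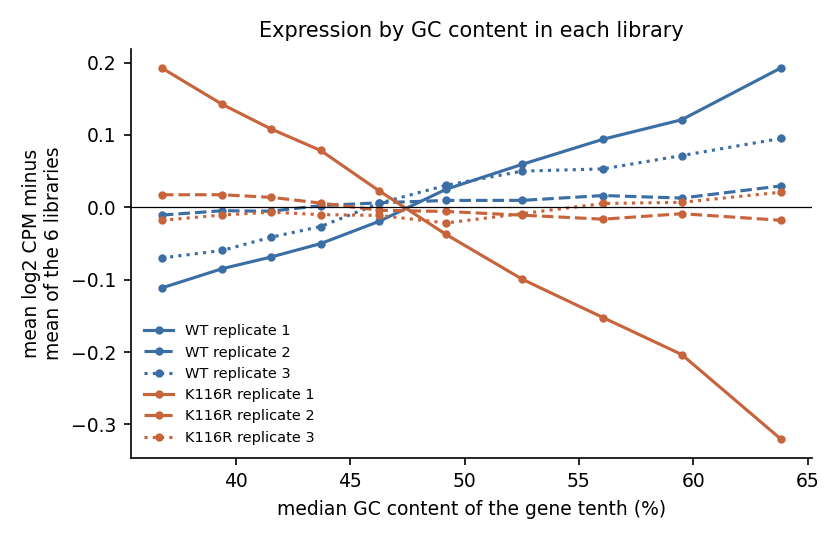
Mean deviation of log2 CPM from the mean of the 6 libraries (vertical axis) in 10 bins of 11156 protein-coding genes ordered by GC content (horizontal axis, percent), with 1 line per library. K116R replicate 1 goes from 0.192 in the bin of lowest GC content to -0.320 in the highest, WT replicate 1 from -0.111 to 0.193, and WT replicate 2 from -0.0107 to 0.0296. K116R replicate 2 goes from 0.0173 to -0.0179, K116R replicate 3 from -0.0179 to 0.0209, and WT replicate 3 from -0.0699 to 0.0952.

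The protein-coding genes with the largest rises, among those with a mean of at least 2 CPM and no overlap between groups, were RBM34, EIF5AL1, CALCR, SWT1, RPS10, EBLN2, PDE4D, CTGF, TXNIP and PLEKHH2, from 2.43-fold for RBM34 to 1.76-fold for PLEKHH2. TXNIP, an inhibitor of thioredoxin and of glucose uptake, went from 7.04 ± 0.602 to 12.7 ± 1.91 CPM (SD, n = 3, log2 fold change 0.85, edgeR adjusted p = 9.2e-04). RBM34 shares 51.5% of its exon bases with ARID4B on the same strand and RPS10 shares 39.4% with the read-through gene RPS10-NUDT3, and EIF5AL1 is an intronless near-copy of EIF5A, so the reads of these 3 genes could be assigned differently. EIF5AL1 lost its call without WT replicate 1 (edgeR adjusted p = 0.088). CALCR lost it without WT replicate 1, 2 or 3 (edgeR adjusted p = 0.069, 0.060 and 0.14) or K116R replicate 3 (0.092), and PDE4D without WT replicate 1, 2 or 3 (0.13, 0.078 and 0.11) or K116R replicate 1 (0.23). The largest falls were in IFI6, PDXP, TMEM141, MMP9, COX6A1, FAM207A, GUCA1B, IFITM1, UQCRHL and HIRIP3, from 0.291 of the WT level for IFI6 to 0.501 for HIRIP3. IFI6 and IFITM1 are interferon-induced membrane proteins. IFI6 went from 4.89 ± 0.558 to 1.42 ± 0.443 CPM (SD, n = 3, edgeR adjusted p = 1.7e-04), and IFITM1 from 15.9 ± 2.25 to 7.73 ± 1.70 CPM (SD, n = 3, edgeR adjusted p = 2.6e-04). MMP9, a gelatinase that docks on CD44, went from 4.80 ± 1.70 to 2.16 ± 0.261 CPM (SD, n = 3, edgeR adjusted p = 0.0064) and was not called without WT replicate 1 (edgeR adjusted p = 0.11), nor was GUCA1B (0.095). PDXP shares 62.6% of its exon bases with Z83844.3, IFITM1 32.5% with IFITM2, TMEM141 16.5% with AL355987.3 and COX6A1 13.0% with AL021546.1 on the same strand. HIRIP3 and MMP9 lie opposite INO80E and SLC12A5-AS1 over 29.1% and 18.4% of their exon bases, and UQCRHL is an intronless copy of UQCRH. PDE4D was also not called by limma-voom (adjusted p = 0.056), nor with the GC correction without K116R replicate 1 (edgeR adjusted p = 0.28). With the GC correction over all libraries all 20 of these genes were called.

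Genes of the integrated stress response, which ATF4 controls when translation initiation is restrained, were lower with K116R. Of 27 measured members 14 fell, 1 rose and 12 did not pass the test, and adjusted over the list alone 15 fell and 1 rose. The list's median log2 fold change was -0.30 (camera adjusted p = 6.7e-13, adjusted p = 0.063 with an estimated correlation). PPP1R15A, the phosphatase subunit that restores translation, went from 68.6 ± 6.28 to 37.8 ± 7.08 CPM (SD, n = 3, log2 fold change -0.86, edgeR adjusted p = 2.6e-04). SLC7A5 and SLC3A2, the light and heavy chains of a neutral amino acid transporter, fell by 0.54 and 0.38 on the log2 scale, and STC2, a secreted glycoprotein, fell by 0.39. Unfolded protein response genes of the endoplasmic reticulum moved the same way, with 9 of 22 lower, none higher and 13 not passing, and 14 lower when adjusted over the list alone. Their median was -0.21 (camera adjusted p = 1.9e-08, adjusted p = 0.063 with an estimated correlation). The chaperones CALR and HYOU1 each had a log2 fold change of -0.36, the disulfide isomerase PDIA4 one of -0.30 and the secreted factor MANF one of -0.52. Of 26 genes of the NRF2 antioxidant response and ferroptosis, 11 fell, none rose and 15 did not pass, and 13 fell when adjusted over the list alone (median -0.25, camera adjusted p = 1.1e-06, adjusted p = 0.074 with an estimated correlation). TXNRD1, thioredoxin reductase, went from 329 ± 8.93 to 240 ± 6.15 CPM (SD, n = 3, log2 fold change -0.46, edgeR adjusted p = 2.0e-05), and FTL, ferritin light chain with 16 annotated pseudogenes of its name, had a log2 fold change of -0.38, and of -0.17 with a gene-length correction (edgeR adjusted p = 0.057). With the GC correction 13 ATF4, 14 unfolded protein response and 11 NRF2 genes fell, and the first 2 lists passed with an estimated correlation as well (adjusted p = 0.016 for each), which the NRF2 list did not (adjusted p = 0.10). With GC and length correction the NRF2 median was -0.15.

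**Figure D3:**
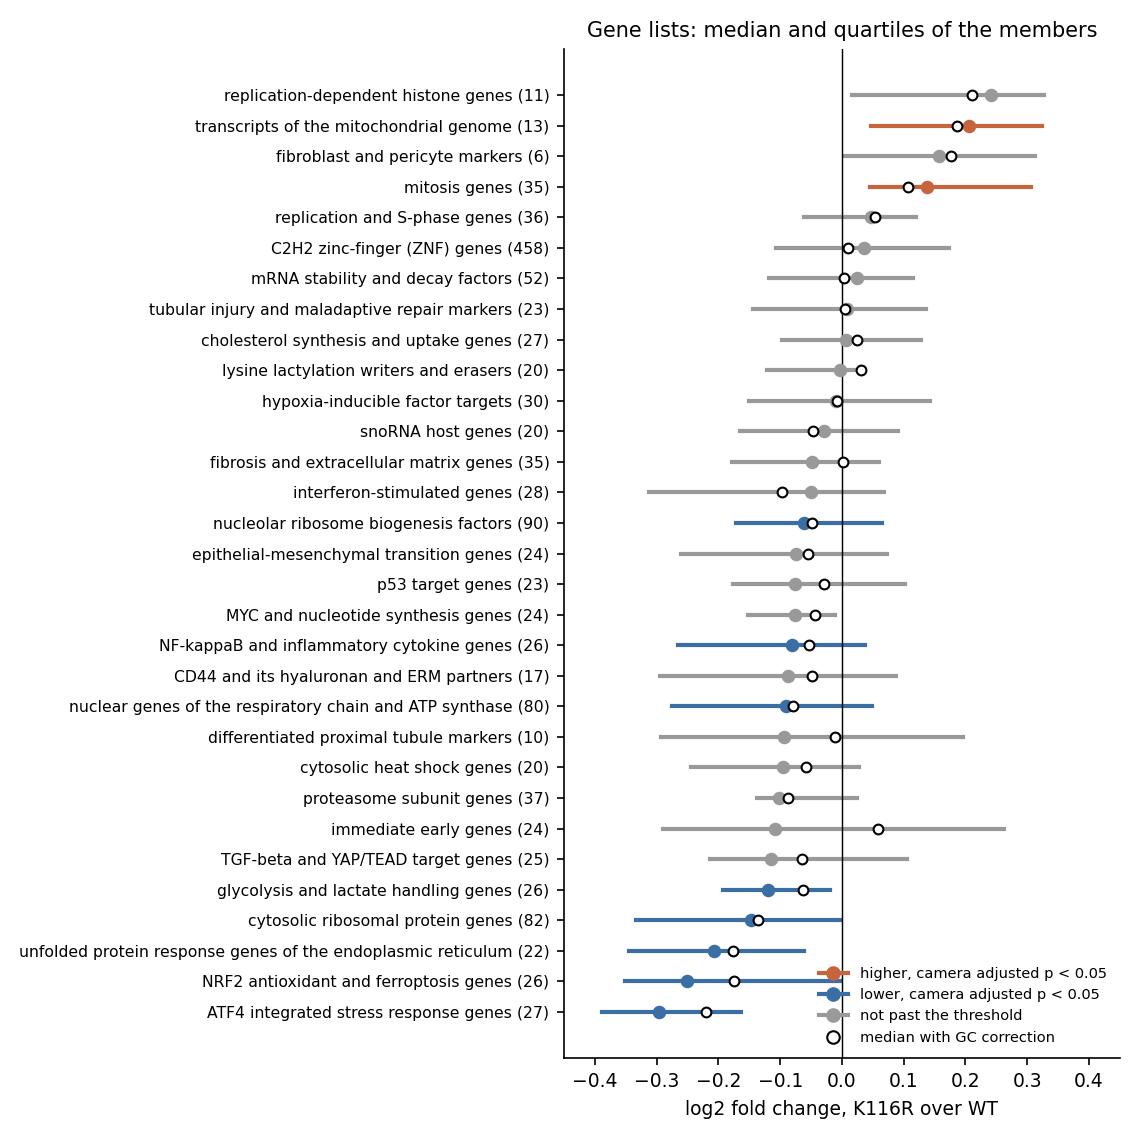
Median log2 fold change, K116R over WT (filled circle), with the quartiles of the members (bar) for the 31 gene lists that had at least 5 genes tested, and the median after GC correction (open circle). The number of genes tested stands in parentheses. ATF4 genes had the lowest median, -0.30, and replication-dependent histone genes, which did not pass the threshold, the highest, 0.24.

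Genes of the fibrotic matrix and of TGF-beta signalling moved in both directions. Of 35 fibrosis and matrix genes 7 fell, 3 rose and 25 did not pass, and adjusted over the list alone 9 fell and 4 rose. As a list they did not pass (median -0.05, camera adjusted p = 0.055, adjusted p = 0.37 with an estimated correlation). The list passed without WT replicate 1 (camera adjusted p = 0.048) or K116R replicate 2 (0.024) and on limma-voom values (0.030), and after GC correction 8 fell and 6 rose (camera adjusted p = 0.74), with a median of 0.00098. LAMB3, a laminin chain of the basement membrane, went from 285 ± 8.10 to 225 ± 14.2 CPM (SD, n = 3, log2 fold change -0.34, edgeR adjusted p = 8.0e-04). THBS2, a matricellular thrombospondin, had a log2 fold change of 0.26 (edgeR adjusted p = 0.015), and without WT replicate 1 or 3 its adjusted p was 0.13 and 0.083. Of 25 TGF-beta and YAP/TEAD target genes 8 fell, 2 rose and 15 did not pass (adjusted over the list alone 9 fell and 5 rose, median -0.11, camera adjusted p = 0.18, and with the GC correction median -0.07, camera adjusted p = 0.42). By fry that list passed (adjusted p = 0.022), and camera with an estimated correlation gave an adjusted p of 0.30. CTGF was one of the genes that rose, while the receptor kinase AXL and the TGF-beta feedback inhibitor PMEPA1 fell by 0.42 and 0.44 on the log2 scale (edgeR adjusted p = 1.5e-04 and 0.0011). Among 17 genes of CD44 and its partners 3 fell and 1 rose (adjusted over the list alone 4 and 2, median -0.09, camera adjusted p = 0.13, and with the GC correction median -0.05, camera adjusted p = 0.10), with CD44, MMP9 and MMP14, a membrane-bound metalloproteinase, among the lower ones. MMP14 went from 196 ± 7.53 to 138 ± 10.1 CPM (SD, n = 3, log2 fold change -0.50, edgeR adjusted p = 4.3e-05). Of 24 epithelial-mesenchymal transition genes 3 fell and none rose (adjusted over the list alone 3 and 1, median -0.07, camera adjusted p = 0.11, 0.041 with the GC correction, and 0.25 with that and an estimated correlation), namely ITGA5, CLDN4 and GREM1, with log2 fold changes of -0.39, -0.46 and -0.42. ITGA5 is the fibronectin receptor chain, CLDN4 a tight-junction protein of epithelia and GREM1 a secreted BMP antagonist. The transition list mixes epithelial and mesenchymal genes, so its direction does not tell whether the transition was stronger or weaker. Of 23 tubular injury markers 4 fell and 1 rose (adjusted over the list alone 4 and 2, camera adjusted p = 0.88). The adhesion molecule ICAM1, with 23.6% of its exon bases opposite other genes, fell from 198 ± 6.49 to 149 ± 16.3 CPM (SD, n = 3, edgeR adjusted p = 8.9e-04), and the integrin chain ITGB8 had a log2 fold change of 0.50 (edgeR adjusted p = 2.9e-05). The median and mean of the injury list were positive (0.0086 and 0.026) and the direction of its camera test negative, and with library size in place of TMM scaling the median was -0.02.

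Ribosomal protein genes were lower with K116R. Of 82 measured, 27 fell, 2 rose and 53 did not pass, and adjusted over the list alone 37 fell and 3 rose (median -0.15, camera adjusted p = 2.7e-12, adjusted p = 0.30 with an estimated correlation of 0.22 between the genes). RPL39 went from 106 ± 2.33 to 65.1 ± 7.46 CPM and RPS3 from 335 ± 15.4 to 260 ± 5.97 CPM (SD, n = 3, edgeR adjusted p = 6.6e-06 and 3.0e-04). RPL39 and RPS3 have 15 and 4 annotated pseudogenes of their names, with which reads could be shared. After GC correction 32 of the ribosomal protein genes fell and 2 rose, and with GC and length correction the list's median was -0.09. Nucleolar ribosome biogenesis factors, to which DDX18 belongs, were also lower, with 10 of 90 lower, 3 higher and 77 not passing, the same counts when adjusted over the list alone (median -0.06, camera adjusted p = 0.021, adjusted p = 0.12 with an estimated correlation). DDX18, the gene that was depleted and put back, is itself 1 of the 10 lower genes and part of the list test. A test of the list without DDX18 was not run. Without K116R replicate 3 that list did not pass (camera adjusted p = 0.056), and after GC correction 7 fell and 2 rose. NOP10, a subunit of the pseudouridylation complex, had a log2 fold change of -0.81 (edgeR adjusted p = 0.0078).

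Mitochondrially encoded transcripts were higher with K116R and nuclear genes of the same complexes were lower. The mitochondrial share of all counts was 17.9% in K116R replicate 1, within the WT range of 17.2% to 18.7%. It was above that range in K116R replicates 2 and 3 (20.7% and 21.1%). The mitochondrial list had been fixed as a marker of RNA quality, and the cause of its rise was not tested. Of 13 mitochondrial mRNAs 6 rose, none fell and 7 did not pass, and 7 rose when adjusted over the list alone (median 0.21, camera adjusted p = 4.0e-06, adjusted p = 0.33 with an estimated correlation of 0.84), and by fry the list did not pass (adjusted p = 0.11). With GC and length correction the median was 0.35. MT-ND6, the only one encoded on the light strand, went from 1306 ± 58.1 to 1902 ± 177 CPM (SD, n = 3, edgeR adjusted p = 1.3e-05), and MT-ATP6 from 8365 ± 479 to 10578 ± 744 CPM (SD, n = 3, edgeR adjusted p = 9.2e-04). MT-CO1, at 51492 ± 2898 and 64430 ± 4657 CPM (SD, n = 3), had an edgeR adjusted p of 0.0017 and of 0.052 without WT replicate 3. The 5 most abundant genes that changed were MT-CO1, MT-ND4, MT-ATP6, MT-ND5 and MT-ND4L, with log2 fold changes of 0.32, 0.29, 0.34, 0.19 and 0.35. MT-ND4 lost its call without WT replicate 1 or 3 (edgeR adjusted p = 0.053 and 0.076), and MT-ND5 without WT replicate 1, 2 or 3 (0.22, 0.069 and 0.18) or K116R replicate 2 or 3 (0.099 and 0.19). After GC correction 3 of the 13 rose and MT-ND6 was not among them (log2 fold change 0.48 in place of 0.54, edgeR adjusted p = 0.062), nor were MT-ND4 and MT-ND5 (0.084 and 0.24). Of 80 nuclear genes of the respiratory chain and ATP synthase 12 fell, 2 rose and 66 did not pass, and adjusted over the list alone 14 fell and 2 rose (median -0.09, camera adjusted p = 0.0023, adjusted p = 0.12 with an estimated correlation, and 0.065 by camera after GC and length correction, with a median of -0.04). UQCRB and ATP5MF, small subunits of complex III and of ATP synthase, had log2 fold changes of -0.58 and -0.51, and with the GC correction 11 of the nuclear genes fell and 1 rose. Of 26 genes of glycolysis and lactate handling 3 fell, none rose and 23 did not pass (adjusted over the list alone 6 fell and 1 rose). Their median was -0.12 (camera adjusted p = 0.034, adjusted p = 0.30 with an estimated correlation), and the list did not pass without WT replicate 3 (camera adjusted p = 0.10) or K116R replicate 3 (0.082). With the GC correction 4 fell and none rose, and the median was -0.06. PKM, pyruvate kinase, went from 1599 ± 80.4 to 1357 ± 46.9 CPM (SD, n = 3, edgeR adjusted p = 0.0068, and 0.074 and 0.096 without WT replicates 1 and 3). Of 30 targets of hypoxia-inducible factor 4 fell and 2 rose (adjusted over the list alone 5 and 4, camera adjusted p = 0.69). The transcription factor HIF1A had a log2 fold change of 0.36 and the glucose transporter SLC2A1 one of -0.34 (edgeR adjusted p = 7.0e-04 and 7.6e-04).

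Mitosis genes were higher with K116R. Of 35 measured, 11 rose, none fell and 24 did not pass, and adjusted over the list alone 14 rose and 1 fell (median 0.14, camera adjusted p = 4.0e-06, adjusted p = 0.30 with an estimated correlation). The kinesins KIF20A and CENPE went from 56.8 ± 1.02 to 72.6 ± 4.21 CPM and from 68.3 ± 7.47 to 90.0 ± 8.91 CPM (SD, n = 3, edgeR adjusted p = 0.0038 and 0.0047). Without WT replicate 3 their edgeR adjusted p was 0.051 and 0.063, and CENPE had 0.057 without WT replicate 1. After GC correction 12 rose and 1 fell. Of 36 replication and S-phase genes 4 rose and 2 fell (adjusted over the list alone 4 and 3, camera adjusted p = 0.20, 0.049 with the GC correction, and 0.30 with that and an estimated correlation), with the repressor E2F8 at a log2 fold change of 0.48 (edgeR adjusted p = 0.0055, and 0.056 without WT replicate 1).

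Of 26 NF-kappaB and inflammatory cytokine genes 6 fell, none rose and 20 did not pass, and adjusted over the list alone 6 fell and 1 rose. Their median was -0.08 (camera adjusted p = 0.040, adjusted p = 0.30 with an estimated correlation), and the list missed the threshold without K116R replicate 2 (camera adjusted p = 0.0503), K116R replicate 3 (0.082), WT replicate 1 (0.077) or WT replicate 3 (0.072). With the GC correction 6 fell and 2 rose (median -0.05, camera adjusted p = 0.041), and the list missed the threshold with GC and length correction (median -0.03, camera adjusted p = 0.071) and on limma-voom values (0.067). ICAM1 and RELB, a subunit of the noncanonical pathway, were among the lower genes, with log2 fold changes of -0.41 and -0.58 (edgeR adjusted p = 8.9e-04 and 0.0011). Of 28 interferon-stimulated genes 5 fell and 3 rose (adjusted over the list alone 6 and 3, camera adjusted p = 0.14, 0.30 with an estimated correlation, and fry adjusted p = 0.022). OAS2 had a log2 fold change of -1.92 at 1.30 ± 0.279 against 0.336 ± 0.085 CPM (SD, n = 3, edgeR adjusted p = 0.011). Of 24 immediate early genes 6 fell, 5 rose and 13 did not pass (adjusted over the list alone 7 and 6, camera adjusted p = 0.88), and the direction of this list turned with the GC correction (camera adjusted p = 0.16). The phosphatases DUSP5 and DUSP1, which switch off MAP kinases, and KLF10, a TGF-beta-inducible transcription factor, had log2 fold changes of 0.60, 0.47 and 0.55 (edgeR adjusted p = 7.2e-05, 9.3e-04 and 1.1e-04). FOSL2, an AP-1 subunit, had one of -0.31 (edgeR adjusted p = 0.0020). Of 23 p53 targets 5 fell and 1 rose (adjusted over the list alone 5 and 2, camera adjusted p = 0.19), and GDF15, a stress-induced cytokine, went from 336 ± 15.6 to 242 ± 25.2 CPM (SD, n = 3, edgeR adjusted p = 1.6e-04).

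The other lists did not pass the camera test. Of 52 mRNA stability and decay factors 3 rose and 1 fell (also when adjusted over the list alone, camera adjusted p = 0.56, median 0.02, or 0.0028 with the GC correction, and mean -0.0017). ZC3H12A, an endonuclease that degrades cytokine mRNAs, was the member with the smallest p, at 45.4 ± 2.81 and 63.7 ± 8.06 CPM (SD, n = 3, log2 fold change 0.49, edgeR adjusted p = 0.0015). Of 20 writers and erasers of lysine lactylation 1 fell and none rose (also when adjusted over the list alone, camera adjusted p = 0.53), namely AARS, the cytosolic alanyl-tRNA synthetase, at a log2 fold change of -0.29 (edgeR adjusted p = 0.0028). Proteasome subunits had 5 lower and 1 higher of 37 (adjusted over the list alone 6 and 1, camera adjusted p = 0.055), and the list passed without K116R replicate 1 (camera adjusted p = 0.018) or WT replicate 1 (0.048), with the GC correction (0.0054) and by fry (adjusted p = 0.0054). With an estimated correlation it did not pass (camera adjusted p = 0.28, and 0.10 with the GC correction). MYC and nucleotide synthesis genes had 3 lower of 24 (adjusted over the list alone 4, camera adjusted p = 0.060, 0.30 with an estimated correlation, and fry adjusted p = 0.023). Heat shock genes had 1 lower and 1 higher of 20 (adjusted over the list alone 2 and 1, camera adjusted p = 0.19). Cholesterol genes had 2 higher and 1 lower of 27 (also when adjusted over the list alone, camera adjusted p = 0.53, 0.041 with the GC correction, 0.42 with that and an estimated correlation, and 0.064 with GC and length correction), and snoRNA host genes 2 higher and 1 lower of 20 (also when adjusted over the list alone, camera adjusted p = 0.77). Histone genes had 1 lower of 11 (also when adjusted over the list alone, camera adjusted p = 0.48), and C2H2 zinc-finger genes 22 higher and 11 lower of 458 (adjusted over the list alone 12 and 9, camera adjusted p = 0.17). Among markers of cell types, differentiated proximal tubule had 1 lower of 10 tested of 26 listed (adjusted over the list alone 2, camera adjusted p = 0.53). Fibroblast and pericyte markers had 1 higher of 6 tested (also when adjusted over the list alone, camera adjusted p = 0.11, and 0.029 without K116R replicate 1). This was RGS5, at a log2 fold change of 0.41, under 1 of the 2 gene identifiers that carry the symbol. Distal nephron, endothelial and leukocyte markers had 3, 3 and 2 genes expressed enough to test, too few for a list test, and 1 endothelial marker, EGFL7, was lower (log2 fold change -0.58, edgeR adjusted p = 0.041, chosen after its value was seen), a call lost with the GC correction (log2 fold change -0.35, edgeR adjusted p = 0.16).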

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

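The alternatives with a GC correction were chosen after seeing the data; the others were planned. Among fits on counts with all libraries, the number of changed genes lay between 1039 and 2173, CD44 between -0.35 and -0.29 and DDX18 between -1.03 and -0.91 (log2), each past the threshold. With FPKM values the changed genes numbered 86 (pseudocount 1), 99 (pseudocount 0.1) and 0 (limma, no filter, with 3880 at an unadjusted p under 0.05, where edgeR on counts called 1524 and DESeq2 1405), of which 32, 39 and 0 were higher, 54, 60 and 0 lower, and 10, 14 and 0 at least 2-fold. CD44 then had -0.297, -0.308 and -0.297 (limma adjusted p = 0.069, 0.068 and 0.144, over all alternatives 1.0e-09 to 0.144), and DDX18 without a filter -0.869 (limma adjusted p = 0.061, over all alternatives 2.3e-46 to 0.061). Higher genes numbered 463 with library size only, 1122 with the GC correction and 1153 with GC and length correction. Genes changed at least 2-fold numbered 16 with DESeq2, 27 among protein-coding genes only, where fewer genes were tested, and 100 with the gene-length correction. Lists past the threshold numbered 0 with an estimated correlation (fry 13) and 2 with the GC correction and an estimated correlation. For the other changes the cause was not tested.

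Same-numbered samples had correlations of their deviations of -0.35, -0.22 and 0.016, and differently numbered ones lay between -0.28 and 0.36. The GC trends of the libraries enter these values. They therefore cannot tell whether same-numbered samples share a culture or a batch. With the replicate block 1086 genes changed, 439 of them higher, with the block and GC correction 2017 and 1063 higher, and with the block and gene-length correction 1039 and 480 lower. The NF-kappaB list missed the threshold with the block (camera adjusted p = 0.058), COX6A1 with the block and GC correction (edgeR adjusted p = 0.10), and GUCA1B and PDE4D with the block and gene-length correction (0.052 and 0.059).

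Without 1 library each, changed genes ranged from 408 to 1697, higher genes from 161 to 748, lower genes from 236 to 959, 2-fold changes from 24 to 72, CD44 from -0.343 to -0.279, DDX18 from -0.972 to -0.878, and lists past the threshold from 7 to 12. The lowest counts came without WT replicate 1 (408 changed, 236 lower, 24 at 2-fold) and WT replicate 3 (161 higher), and the 7 lists without K116R replicate 3. These fits have fewer samples.

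Some lists that did not pass turned direction in some alternatives. Tubular injury turned with GC and length correction (camera adjusted p = 0.697) and without K116R replicate 3 (0.948). Without 1 library each it had 0.751 to 0.967. The snoRNA hosts turned only without K116R replicate 3 (0.948), in a range of 0.634 to 0.948 without 1 library each. Lactylation turned with the GC correction (0.902), with an estimated correlation too (0.918), and without K116R replicate 1 (0.963). Its range without 1 library each was 0.338 to 0.963. Genes of mRNA stability and zinc-finger genes turned with GC and length correction (0.756 each). Immediate early genes turned with the GC correction (0.162), with GC and length correction (0.0735) and with the GC correction and an estimated correlation (0.421). Without 1 library each they had 0.463 to 0.774. The cause was not tested. Of 130 genes named or listed for naming, 0 turned direction in any alternative, 92 were called in all fits on counts with all libraries, and 72 in all 6 fits without 1 library. Most of these genes were chosen because they passed the main test on the same samples, so a kept direction is not independent support. On FPKM DDX18 and 24 of the 128 genes other than DDX18 and CD44 kept their call with pseudocount 1, and as many with 0.1, and without a filter no gene was called. At this depth and n, the smallest simulated changes were recovered for 38% of genes, for 14% with a GC slope in K116R replicate 1, and for 30% with that slope and the GC correction. Genes with low counts were not among those changed in the simulation.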

Other observations

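The tests of the GC trend, of the ATF4 and unfolded protein response lists and of DDX18 RNA were chosen after the results were seen, as were the noncoding genes named here. The splits of the samples and the test of AU-rich elements were not, except for their corrections. The GC correction of the splits and the GC and length correction in the AU-rich test were chosen after seeing the data. NEAT1, the scaffold RNA of paraspeckles, went from 940 ± 79.8 to 1201 ± 45.7 CPM (SD, n = 3, log2 fold change 0.35, edgeR adjusted p = 6.4e-04). MALAT1, an abundant RNA of nuclear speckles, went from 2306 ± 139 to 2738 ± 74.5 CPM (SD, n = 3, log2 fold change 0.25, edgeR adjusted p = 0.0053), with an adjusted p of 0.063 without WT replicate 1 and 0.10 without WT replicate 3. Of 791 long intergenic noncoding RNAs 20 were higher and 5 lower, of 1153 antisense RNAs 20 and 11, of 41 snoRNAs 5 and 0, and of 29 snRNAs 4 and 0, beside 702 and 822 of all 16958 genes tested. All 4 snRNA genes called carry pseudogene symbols, so these counts show no rise of functional snRNAs. The 5 snoRNA genes called were at low levels. Whether reads of other genes were counted at these snRNA and snoRNA loci was not tested. Among 21 mitochondrial tRNA genes 3 rose and 6 fell, and 6 of these 9 calls depended on single libraries. Without WT replicate 1, MT-TH, MT-TL2, MT-TI, MT-TM and MT-TP lost their calls (edgeR adjusted p = 0.091, 0.083, 0.062, 0.058 and 0.11). So did MT-TH and MT-TI without WT replicate 2 (0.058 and 0.061), MT-TI, MT-TP and MT-TT without WT replicate 3 (0.088, 0.098 and 0.089), MT-TH, MT-TI and MT-TP without K116R replicate 2 (0.059, 0.080 and 0.056), and MT-TP without K116R replicate 3 (0.056). With the GC correction MT-TH, MT-TP and MT-TT had log2 fold changes of -1.64, 0.21 and 0.48, in place of -1.52, 0.34 and 0.59, and were not called (edgeR adjusted p = 0.12, 0.58 and 0.26), nor with the gene-length correction were MT-TL2 and MT-TI (0.075 and 0.24). MT-TS2 and MT-TG had log2 fold changes of -2.05 and -1.03 and MT-TF one of 1.05 (edgeR adjusted p = 6.6e-04, 6.9e-04 and 0.0033), at mean levels between 0.672 and 11.1 CPM. These genes adjoin other mitochondrial genes, and the rule that assigned reads at their ends is not given in the sources used here.

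GC-rich genes were lower with K116R in the group comparison, with a rho of -0.53 between log2 fold change and GC content across genes. Not all libraries shared the trend. The per-library rho was -0.72 in K116R replicate 1, 0.61 in WT replicate 1 and 0.40 in WT replicate 3. It was 0.083 in K116R replicate 3 and 0.096 in WT replicate 2, a narrow gap on which the separation of the groups rests. GC bias in K116R replicate 1 alone is argued against by a rho of -0.308 without that library. After GC correction 75.7% of the called genes kept call and direction, and 72.8% after GC and length correction. This argues only weakly against the trend as the whole cause of the called genes. The correction was fitted on the same libraries and removes only a smooth trend. It also raised the number of calls from 1524 to 2146, which makes a call easier to keep. Whether the trend may come from library preparation or from the form of DDX18 cannot be told apart: the exact permutation p of the per-library correlations is 0.1, the smallest that 3 against 3 allows, and the labels name no batch.

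ATF4 and unfolded protein response genes were lower together. GC and length bias as the whole cause is argued against by medians of -0.213 (95% bootstrap interval -0.318 to -0.148) and -0.181 (-0.237 to -0.141) after both corrections. Each interval given here resampled the genes of a list, not the libraries, so it does not measure the spread between samples. K116R replicate 1 as the only source is argued against by medians of -0.272 (-0.369 to -0.213) and -0.196 (-0.296 to -0.132) without it. A weaker stress response in cells with K116R may underlie this, as a hypothesis found and tested on the same data, and neither list passed with an estimated correlation before GC correction (camera adjusted p = 0.063 for each). A difference between cultures in nutrients or density was not tested.

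DDX18 RNA was lower with K116R. Library scaling as the cause is argued against by a log2 fold change of -0.912, the one nearest to 0 over 4 scalings. The amount of DDX18 RNA and the amino acid change cannot be told apart as sources of the other changes, because 0 K116R libraries had DDX18 in the WT range. A lower transfected dose or a less stable transcript could each give the lower level, and the counts do not separate construct from endogenous RNA.

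The 10 splits of 6 samples into 3 and 3 cannot give a share under 0.05. The real split gave 1524 changed genes and the highest other 0 by edgeR (4041 and 1166 at an unadjusted p under 0.05), so 1 split of 10 gave as many. With the GC correction the real split gave 2146 and the highest other 0 (4331 and 676 at an unadjusted p under 0.05), again 1 of 10.

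The series title names CD44 mRNA stability, and one hypothesis was that genes with AU-rich elements in the 3′ UTR fell with CD44. Of 12473 genes searched, 1044 held the nonamer TTATTTATT. Fold changes with GC and length correction were compared with those of genes without it, matched on 3′ UTR length, GC content and expression. The mean log2 fold difference was -0.0045 (permutation p = 0.525 over 2000 permutations, 95% of permuted differences between -0.0126 and 0.0136). The searched CD44 3′ UTR of 3069 bases held 0 copies, so the test does not bear on the lower RNA of CD44 itself. The data gave no sign of lower RNA of such genes with K116R, and steady-state counts do not measure stability.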
